A study of Rattus norvegicus with 8 samples.

How the data were processed

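The series holds 8 Affymetrix arrays of perfused liver from male Wistar rats, 4 from perfusion with normoosmotic and 4 with hypoosmotic buffer, all at 180 min. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was isolated from homogenised liver with a column kit, and 1 µg of total RNA was turned into biotinylated sense-strand cDNA by a whole-transcript assay that primes along the length of transcripts.

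The authors deposited a table of log2 expression values with 27596 probe sets and 8 arrays, given with 2 decimals. Per the submitters' processing notes, Affymetrix Expression Console, Transcriptome Analysis Console 4.0 and RMA were used, with no role or order stated. RMA is known to correct background, equalise the distributions of the arrays and summarise probes on the log2 scale, so a change shared by most genes would be removed. The array medians of the deposited log2 values lay between 3.92 and 4.05. Which probes were masked and on which genome build they were designed are not given in the sources used here, so no coordinates are printed. Scanner files were not used here, so the background correction could not be run another way, and no detection calls or slide and scan information entered the analysis.

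Probe sets were named through the platform annotation of 2016. Of the probe sets, 15316 had 1 gene symbol, 317 had several and 11963 were not named here. Symbols were updated through a table of rat genes, where 15285 were found by gene identifier, 6 by accession and 25 were kept as annotated, which changed 2 symbols. For the 528 genes with more than 1 probe set, the one with the highest mean over all 8 arrays was used, which left 14511 genes.

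Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term) on the deposited log2 values. The p-values, from both tails, were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. A change is the hypoosmotic mean minus the normoosmotic mean on the log2 scale with its limma standard error (SE), and levels are means ± SD with n = 4. In all, 38 gene lists, 28 of pathways and 10 of cell types, were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 38 lists. Each list had at least 5 measured members, and 615 of the 691 list entries were measured. Members that passed are counted over all genes and adjusted over the list alone. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the plots.

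The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap, leaving out symbols that are only locus numbers, of which 0 had changed. It added 12 genes to be given whatever their value, of which 11 were measured, and up to 4 members with the smallest p-value from each list. Genes named outside it, chosen after their values were seen, were Spry1, Tubb6 and the histone, splicing factor and respiratory chain genes of the other observations.

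The alternatives were the replicate number as a term, an intensity trend with robust variances, array weights, a further quantile normalization, centring of each array on its median, leaving out the 30% dimmest genes, averaging the probe sets of a gene, testing all probe sets together, a minimum fold change of 1.2 (limma treat), and leaving out each array in turn. For the lists, camera with an estimated correlation and fry were added. Families of genes defined by their symbols, and a level below which signal was taken as near background, were added after seeing the data.

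The analysis was tested on simulated data for this comparison, with 14511 genes of which 200 were changed. It recovered 34.0% of the genes changed by 0.5 and 89.0% of those changed by 1 on the log2 scale, with 3 false calls (2.38% of calls). The real comparison called 1026 genes, and the adjustment is stricter when fewer genes change. These shares are therefore not the power of the real comparison. A simulated list of 20 genes moved by 0.4 was called (camera adjusted p = 2.27e-26), and 0 of 50 random lists were. The genes were simulated as independent of each other. The real lists that passed had estimated correlations from 0.12 to 0.54, so this does not show how often such lists are called falsely.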

Results

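Gene expression was measured on 8 Affymetrix whole-transcript arrays, each hybridised with RNA from rat liver perfused with buffer. The livers came from male Wistar rats aged 6 to 10 weeks. For 4 samples the Krebs-Henseleit buffer, a bicarbonate-buffered salt solution, was normoosmotic (305 mosm/L), and for 4 it was hypoosmotic (225 mosm/L), a condition under which liver cells take up water and swell. All 8 arrays belong to the 180 min time point. The deposited values are log2 intensities, with array medians between 3.92 and 4.05, and 14511 named genes were compared. The number of arrays, 4 per group, limits the precision. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The comparison asks which liver transcripts differ after perfusion with the dilute buffer.

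The groups separated along the first principal component, which held 34.7% of the variance, with all 4 normoosmotic arrays on one side and all 4 hypoosmotic arrays on the other. The second component held 18.9% and set hypoosmotic replicate 3 apart, at 28.5, while the other 7 arrays lay between -15.3 and 6.60. Pearson correlations across genes were 0.990 to 0.992 within the normoosmotic group, 0.984 to 0.992 within the hypoosmotic group and 0.980 to 0.990 between groups. Genes are not independent replicates, and these values only describe how alike the arrays were.

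Between hypoosmotic and normoosmotic livers 1026 genes differed, 7.07% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 356 were higher and 670 lower, so 65.3% were falls. With each array centred on its own median the split was 235 higher and 733 lower, or 75.7% falls. The median size of a called change was 0.62 on the log2 scale, and 84 genes changed at least 2-fold, 43 up and 41 down. The 4 values of one group all lay above the 4 of the other for 998 of the 1026 genes, a separation that passing the test itself favours. Over all tested genes this was true of 13.5%, where chance gives 2.86%. The count varied with the array left out. It was 468 without normoosmotic replicate 3, 545 without hypoosmotic replicate 2, 563 without normoosmotic replicate 4 and 626 without normoosmotic replicate 1. It was 675 without normoosmotic replicate 2, 690 without hypoosmotic replicate 1, 915 without hypoosmotic replicate 3 and 1051 without hypoosmotic replicate 4. Fewer arrays also mean less power, so a lower count need not mark the array left out as unusual. Against a minimum fold change of 1.2 the count was 83, with 23 genes higher and 60 lower. Among them were 16 of the 24 genes described next, which had the largest changes among changed genes whose groups did not overlap. Of the 105 changed genes named in the text, 54 passed in all 8 fits that left out 1 array. For the others the number of these fits that each passed is given, with the range of its adjusted p over the 8 and the array whose omission gave the highest.

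The largest rise was in Serpinb2, an inhibitor of plasminogen activators, at 2.61 ± 0.14 (SD, n = 4) in normoosmotic and 4.57 ± 0.78 (SD, n = 4) in hypoosmotic livers, or 3.88-fold. Its normoosmotic level lay below 3.04, the 95th percentile of odorant receptor genes, which were taken as near background, so its fold and its rank were not exact. Timp3, an inhibitor of matrix metalloproteinases, rose 3.85-fold from 6.27 ± 0.49 to 8.22 ± 0.40. The linker histone gene H1f4 rose 3.76-fold from 6.86 ± 0.37 to 8.77 ± 0.41. The smallest adjusted p among the rises described here, 0.000456, was that of Gpcpd1, whose enzyme hydrolyses glycerophosphocholine, a compound that kidney cells accumulate as an organic osmolyte. Gpcpd1 went from 5.55 ± 0.11 to 6.95 ± 0.15, or 2.63-fold. The next rises were those of Rrm2 (ribonucleotide reductase, log2 change 1.47 ± 0.28 SE), Gucy2c (a receptor guanylate cyclase, 1.44 ± 0.26), S1pr1 (a sphingosine 1-phosphate receptor of endothelium, 1.39 ± 0.29) and Cyp3a62 (a cytochrome P450, 1.36 ± 0.27). Scnn1a (the alpha subunit of the epithelial sodium channel, 1.36 ± 0.25), Nptx2 (a neuronal pentraxin, 1.36 ± 0.20), Trim14 (1.35 ± 0.15) and Nags (N-acetylglutamate synthase, 1.32 ± 0.34) completed the 12. Adjusted p-values ranged from 0.000456 to 0.0403. All 4 hypoosmotic values lay above all 4 normoosmotic ones in each of the 12, as the rule for naming them required. Of the 8 fits that left out 1 array, Nags passed in 2 (0.0253 to 0.110, highest without normoosmotic replicate 4), and it did not pass with an intensity trend and robust variances (0.0732). Cyp3a62 and H1f4 belong to families of similar sequence, whose probes can share signal.

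**Figure D1:**
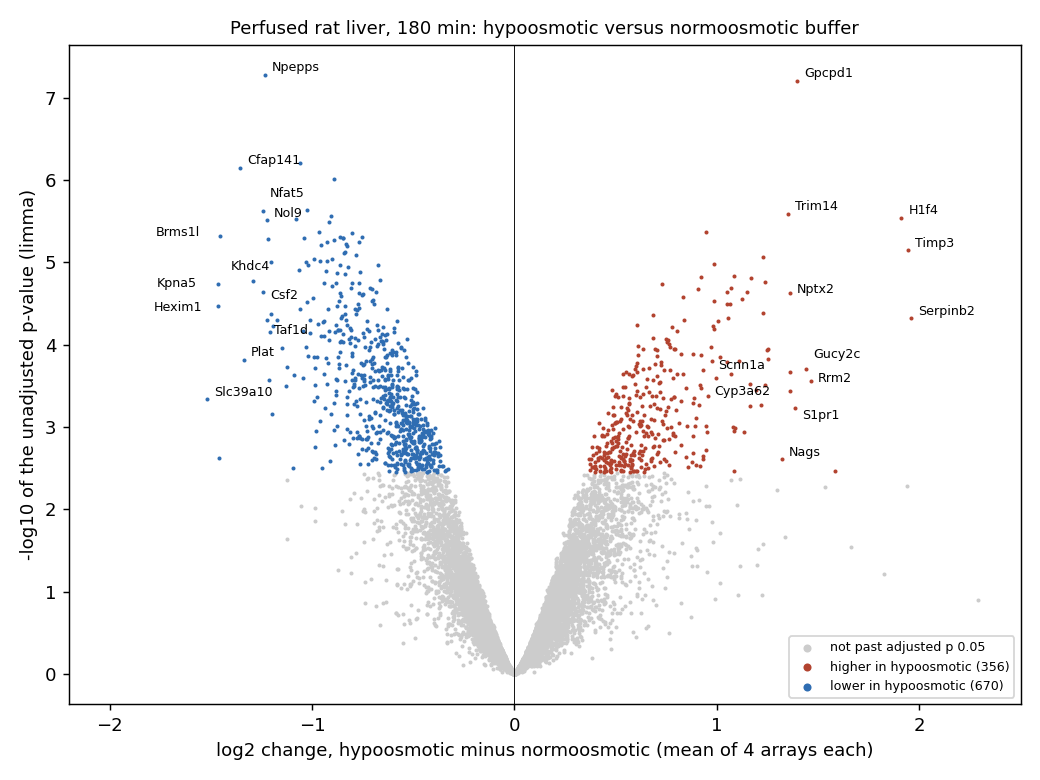
Change of each of the 14511 genes on the log2 scale (hypoosmotic minus normoosmotic, horizontal axis) against the negative log10 of its unadjusted limma p-value (vertical axis), with 4 arrays per group. Red points mark the 356 genes that were higher and blue points the 670 that were lower past an adjusted p of 0.05, and the 12 largest rises and falls with fully separated groups are named, from Serpinb2 at 1.96 to Slc39a10 at -1.52.

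Among the falls with fully separated groups, Slc39a10, a zinc importer, went from 7.49 ± 0.50 to 5.97 ± 0.63 (SD, n = 4 each). Its log2 change was -1.52 with an adjusted p of 0.0161 (limma). It passed in 7 of the 8 fits that left out 1 array (0.0114 to 0.0519, highest without normoosmotic replicate 4). Hexim1, an inhibitor of the elongation kinase P-TEFb, fell by 1.46 ± 0.22 (SE) on the log2 scale. Kpna5, a nuclear import receptor, fell by 1.46 ± 0.20, and Brms1l, a subunit of a histone deacetylase complex, by 1.45 ± 0.18. Cfap141 (-1.36 ± 0.14), Plat (tissue plasminogen activator, -1.34 ± 0.24), Khdc4 (an RNA-binding protein, -1.29 ± 0.18) and Csf2 (the cytokine GM-CSF, -1.24 ± 0.18) came next. Nfat5, the transcription factor that drives the response to high osmolarity, went from 6.94 ± 0.17 to 5.70 ± 0.25, which is 2.37-fold lower (adjusted p = 0.00313). Npepps, a cytosolic aminopeptidase, had the tightest groups, 6.92 ± 0.11 against 5.68 ± 0.05, and the smallest adjusted p of the 12, 0.000456. Nol9 and Taf1d, with roles in ribosomal RNA processing and in transcription by RNA polymerase I, each fell by 1.22 (SE 0.14 and 0.19).

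Of the 8 measured genes of the response to high osmolarity, 3 fell, 0 rose and 5 did not pass. Besides Nfat5, the falls were those of Slc5a3, the sodium-coupled myo-inositol transporter, at 4.67 ± 0.20 against 3.60 ± 0.14 (2.11-fold lower, adjusted p = 0.00313), and Slc38a2, a sodium-coupled amino acid transporter, at 9.98 ± 0.22 against 8.80 ± 0.38 (2.26-fold lower, adjusted p = 0.00646). All 3 passed in each of the 8 fits that left out 1 array. The taurine transporter Slc6a6 had a log2 change of 0.52 ± 0.37 (adjusted p = 0.498), and the kinase gene Sgk1 one of 0.29 ± 0.16 (0.360). For Akr1b1, aldose reductase, which makes the osmolyte sorbitol, the change was 0.52 ± 0.18 with an adjusted p of 0.120, and of 0.0210 without hypoosmotic replicate 1. Adjusted over the list alone, 3 genes fell and 1, Akr1b1, was higher. The list median was 0.09, its mean -0.25 and the set test pointed down (camera, adjusted p = 0.286). Fry also pointed down and did not pass, with a directional p of 0.00185 and an adjusted p of 0.0567. Slc6a12 was not analysed here. Of 19 genes of volume regulation, covering water channels, chloride channels and cotransporters, 1 rose and 1 fell, also when adjusted over the list alone. The potassium-chloride cotransporter gene Slc12a4 fell by 0.59 ± 0.13, and Aqp11, an aquaporin, rose by 0.74 ± 0.19. Of the 8 fits without 1 array, Slc12a4 passed in 4 (0.0160 to 0.0625, highest without normoosmotic replicate 3) and Aqp11 in 1 (0.0273 to 0.115, highest without normoosmotic replicate 3). Aqp11 also did not pass after median centring (0.0609). The kinase gene Wnk1 had a change of -0.36 ± 0.12 (adjusted p = 0.0899), and the set test gave an adjusted p of 0.607.

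**Figure D2:**
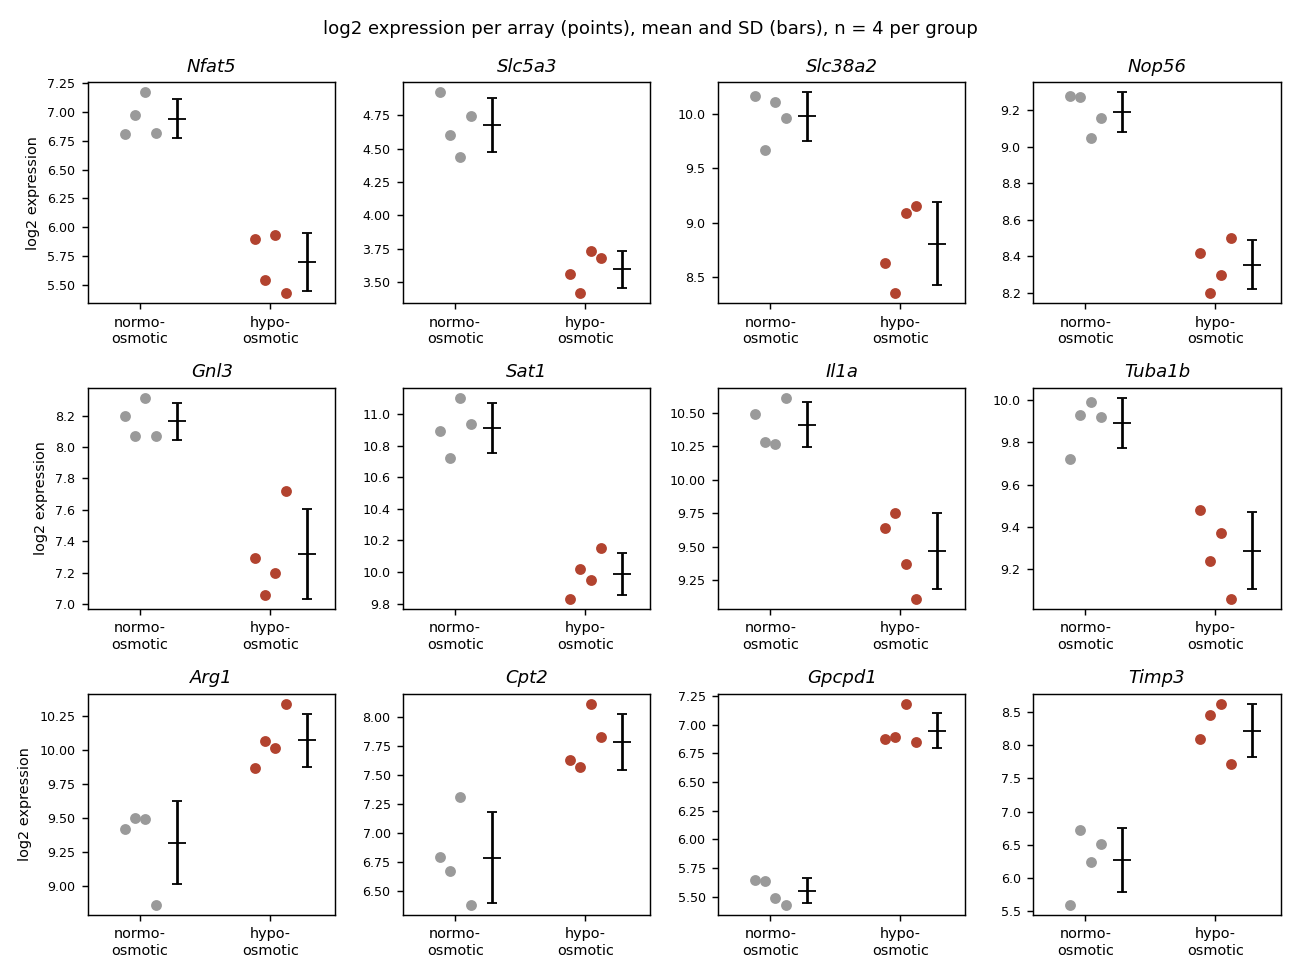
Expression of 12 genes on the log2 scale (vertical axes) in each of the 4 normoosmotic and 4 hypoosmotic arrays (points), with the mean and SD of each group as bars. The groups did not overlap in any panel, with Nfat5, Slc5a3, Slc38a2, Nop56, Gnl3, Sat1, Il1a and Tuba1b lower and Arg1, Cpt2, Gpcpd1 and Timp3 higher in hypoosmotic livers. These 12 are picked examples that each passed in all 8 fits that left out 1 array. Only 54 of the 105 changed genes named in the text did so, and the panels are not typical of the rest.

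Ribosome biogenesis had the smallest adjusted p and the lowest median of the 38 gene lists. The set test gave an adjusted p of 5.74e-15 (camera, preset correlation 0.01), against an adjusted p of 0.735 with an estimated correlation. Adjustment gave that same 0.735 to each list that passed, and the unadjusted p here was 0.0510, the smallest of the 38. By fry the list pointed down with an adjusted p of 0.0567 (directional p). Of its 26 measured members 15 fell and 0 rose, and 21 fell when adjusted over the list alone, with a list median of -0.64. Nop56, a core protein of the box C/D ribonucleoproteins, went from 9.19 ± 0.11 to 8.36 ± 0.13 (SD, n = 4 each). Polr1b, the second largest subunit of RNA polymerase I, fell by 0.86 ± 0.14 (SE), the nucleolar GTPase gene Gnl3 by 0.84 ± 0.14 and Nop14, needed for the small subunit, by 0.77 ± 0.14. All 4 genes passed in each fit that left out 1 array, but the number of members that fell was 5 without normoosmotic replicate 3, 7 without hypoosmotic replicate 2 and 8 without normoosmotic replicate 4. Of 11 polyamine genes 3 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.137). They were Sat1 (-0.93 ± 0.11) and Smox (-0.99 ± 0.20), which acetylate and oxidise polyamines, and the polyamine transporter gene Atp13a3 (-0.62 ± 0.16). The synthesis gene Odc1 had a change of 0.28 ± 0.20 (adjusted p = 0.499). With 1 array left out, Smox passed in 6 (0.0106 to 0.0535, highest without normoosmotic replicate 3) and Atp13a3 in 2 (0.0290 to 0.0969, highest without normoosmotic replicate 3), of 8. Atp13a3 did not pass after a further quantile normalization (0.0559).

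Of 23 measured cytokine and NF-kB target genes, 3 fell and 0 rose, also when adjusted over the list alone, and the list median was -0.29. Il1a (interleukin 1 alpha) went from 10.41 ± 0.17 to 9.47 ± 0.29, Il1b (interleukin 1 beta) from 10.00 ± 0.48 to 8.54 ± 0.86, and the chemokine gene Cxcl2 from 10.28 ± 0.18 to 9.33 ± 0.63 (SD, n = 4 each). The list passed with an adjusted p of 0.00297 (camera), against an adjusted p of 0.735 with an estimated correlation. Il1a passed in each fit that left out 1 array, Il1b in 2 (0.0222 to 0.110, highest without normoosmotic replicate 4) and Cxcl2 in 1 (0.0139 to 0.118, highest without normoosmotic replicate 2), of 8. With an intensity trend and robust variances neither Il1b (0.0849) nor Cxcl2 (0.0595) passed, and Cxcl2 did not after median centring (0.0532). Markers of macrophages, a source of these cytokines, had a median change of 0.30, and 1 of 15 rose. Among 18 acute-phase genes of hepatocytes, 0 passed, also adjusted over the list alone, while 2 had an unadjusted p under 0.05 (limma). The smallest p was that of Cp, ceruloplasmin, with -0.43 ± 0.12 (adjusted p = 0.0558). Cp did pass with an intensity trend (0.0354), after median centring (0.0406) and without the dimmest 30% of genes (0.0465). Their median was -0.02, their mean 0.03 and the test pointed down (camera adjusted p = 0.819).

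Of 19 measured MAP kinase feedback genes, most of them inhibitors of this signalling, 5 fell and 0 rose, also when adjusted over the list alone. They were the phosphatase genes Dusp10 (-0.92 ± 0.17), Dusp6 (-0.56 ± 0.13), Dusp8 (-0.71 ± 0.17) and Dusp16 (-0.70 ± 0.17), and Spry1 (-0.53 ± 0.13), an inhibitor of receptor tyrosine kinase signalling that was named after its value was seen. Dusp1 had a change of 0.17 ± 0.47 (adjusted p = 0.897). Dusp10 passed in all 8 fits without 1 array, Dusp6 in 5 (0.0288 to 0.0697, highest without normoosmotic replicate 4), Dusp8 in 4 (0.0323 to 0.0813, highest without normoosmotic replicate 3), Dusp16 in 2 (0.0179 to 0.105, highest without normoosmotic replicate 3) and Spry1 in 1 (0.0394 to 0.101, highest without normoosmotic replicate 3). The list test gave an adjusted p of 0.137, and of 0.0455 without hypoosmotic replicate 3. Of 25 immediate early genes 1 rose and 3 fell. Klf10, a transcription factor induced by TGF-beta, rose from 5.63 ± 0.31 to 6.68 ± 0.14, while Myc (-0.71 ± 0.16), Ier3 (-0.83 ± 0.19) and Klf6 (-0.55 ± 0.14) fell, and Jun had a change of 0.07 ± 0.18 (adjusted p = 0.891). Adjusted over the list alone the counts were 2 and 4. Klf10 passed in all 8 fits without 1 array, Myc in 4 (0.0165 to 0.0604, highest without normoosmotic replicate 3), Ier3 in 3 (0.0210 to 0.0645, highest without normoosmotic replicate 1) and Klf6 in 2 (0.0355 to 0.123, highest without normoosmotic replicate 3). The list median was -0.02, its mean 0.00 and its adjusted p 0.890.

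Of 20 measured genes of the urea cycle and amino acid breakdown, 4 rose and 0 fell, and 7 rose when adjusted over the list alone, with a median of 0.23. Arg1, the arginase of the urea cycle, went from 9.32 ± 0.31 to 10.07 ± 0.20 (SD, n = 4 each). Cbs, cystathionine beta-synthase, rose by 0.63 ± 0.14 (SE), the mitochondrial ornithine transporter gene Slc25a15 by 0.81 ± 0.18, and Nags, which makes the activator of carbamoyl phosphate synthetase, by 1.32 ± 0.34. The list passed with an adjusted p of 0.00146 (camera), against an adjusted p of 0.735 with an estimated correlation. Arg1 passed in all 8 fits without 1 array, Slc25a15 in 5 (0.0255 to 0.0705, highest without normoosmotic replicate 3), Cbs in 3 (0.0133 to 0.0727, highest without normoosmotic replicate 3) and Nags in 2 (0.0253 to 0.110, highest without normoosmotic replicate 4). The number of members that rose was 1 without normoosmotic replicate 3, normoosmotic replicate 4 or hypoosmotic replicate 2, and 2 without hypoosmotic replicate 1.

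Of 17 PPAR-alpha and fatty acid oxidation genes 1 rose and 0 fell, also when adjusted over the list alone. This was Cpt2, the inner carnitine palmitoyltransferase, from 6.79 ± 0.39 to 7.79 ± 0.24, which passed in all 8 fits without 1 array. Ppara itself had a change of 0.76 ± 0.23 (adjusted p = 0.0780). The list median was 0.20 and its adjusted p 0.0112 (camera), but 0.0683 without normoosmotic replicate 4, and the adjusted p was 0.735 with an estimated correlation. Among 13 genes of gluconeogenesis and fasting 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.579). The coactivator gene Ppargc1a rose from 4.89 ± 0.39 to 6.06 ± 0.41 and the alanine aminotransferase gene Gpt2 by 0.51 ± 0.10 (SE), while Igfbp1, an insulin-repressed binding protein, fell by 0.48 ± 0.10. With 1 array left out, Gpt2 passed in 7 (0.0186 to 0.0512, highest without normoosmotic replicate 3) and Igfbp1 in 7 (0.0193 to 0.0530, highest without normoosmotic replicate 3), of 8. Pck1, the first committed enzyme of gluconeogenesis, was 7.41 ± 0.51 in normoosmotic and 7.79 ± 2.05 in hypoosmotic livers (adjusted p = 0.859), and Tat, tyrosine aminotransferase, 10.69 ± 0.35 and 10.29 ± 0.70 (0.541). Of 16 lipogenesis and glycolysis genes 1 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.137). It was Gpam, which starts glycerolipid synthesis, at 1.09 ± 0.25, and of the 8 fits without 1 array it passed in 3 (0.0222 to 0.0763, highest without normoosmotic replicate 3).

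Of 25 measured cytoskeletal genes, 5 fell and 0 rose, and adjusted over the list alone 9 fell and 2 rose. Actn1, an actin-crosslinking actinin, went from 7.30 ± 0.12 to 6.42 ± 0.19, and the tubulin genes Tubb4b (-0.61 ± 0.11 SE), Tuba1b (-0.60 ± 0.12), Tuba1c (-0.52 ± 0.12) and Tubb6 (-0.63 ± 0.14) fell as well, the last named after its value was seen. Actb, beta-actin, had a change of 0.26 ± 0.16 (adjusted p = 0.426). The list gave an adjusted p of 0.0608 (camera), but 0.00526 without normoosmotic replicate 1, 0.0336 without hypoosmotic replicate 1 and 0.0374 without hypoosmotic replicate 2. Of the 8 fits without 1 array, Tuba1c passed in 4 (0.0277 to 0.0753, highest without normoosmotic replicate 3) and Tubb6 in 3 (0.0239 to 0.0775, highest without normoosmotic replicate 3), and tubulin genes are alike in sequence. Of 15 integrin and adhesion genes 1 rose and 2 fell, or 1 and 3 adjusted over the list alone. Yes1, a Src-family kinase that passed in all 8 fits without 1 array, fell by 0.55 ± 0.11, Itgb1, the beta-1 integrin, by 0.45 ± 0.10 and Itgb3 rose by 0.54 ± 0.12. Of the same 8 fits, Itgb3 passed in 3 (0.0136 to 0.0709, highest without normoosmotic replicate 1) and Itgb1 in 2 (0.0316 to 0.0770, highest without normoosmotic replicate 1). The list test gave 0.137, and 0.0449 without normoosmotic replicate 1. Of 14 YAP/TEAD target genes 2 fell and 0 rose, also adjusted over the list alone, with a median of 0.08, a mean of -0.08 and a test pointing down (camera adjusted p = 0.669). Frmd6, a regulator of the Hippo pathway, fell by 0.70 ± 0.16 and F3, tissue factor, by 0.76 ± 0.18, with calls in 4 (0.0178 to 0.0726, highest without normoosmotic replicate 3) and 4 (0.0358 to 0.0824, highest without normoosmotic replicate 4) of the 8 fits, respectively.

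Of 20 bile acid genes 2 fell and 0 rose, also when adjusted over the list alone. Abcc2, the canalicular export pump for bilirubin conjugates and other organic anions, went from 10.80 ± 0.23 to 10.10 ± 0.12, and passed in all 8 fits without 1 array. Cyp7b1, of the alternative pathway of bile acid synthesis, fell by 0.88 ± 0.20 (SE), and of these fits it passed in 4 (0.0241 to 0.0671, highest without hypoosmotic replicate 2). The list median was 0.07, its mean 0.04 and the test pointed down (camera adjusted p = 0.819). Among 18 cholesterol synthesis genes 0 passed, also adjusted over the list alone, and 2 had an unadjusted p under 0.05 (limma). The smallest p was that of Mvd, at -0.52 ± 0.20 (adjusted p = 0.157). The list gave an adjusted p of 0.607, and of 0.00694 without normoosmotic replicate 4. Of 18 drug metabolism genes 1 rose and 0 fell, also adjusted over the list alone, with a median of 0.35. It was Nr1i2, the pregnane X receptor, at 0.79 ± 0.18, which passed in 2 (0.0219 to 0.0701, highest without normoosmotic replicate 4) of these fits. The list gave an adjusted p of 0.0986 (camera), but 0.0111 without normoosmotic replicate 1 and 0.0455 without hypoosmotic replicate 3.

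Among 14 heat shock genes 2 fell and 1 rose, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.286). The cochaperone gene Chordc1 went from 7.02 ± 0.22 to 6.02 ± 0.23, Hspa4 fell by 0.56 ± 0.10 (SE) and the small heat shock protein gene Hspb1 rose by 1.22 ± 0.25, and of the 8 fits without 1 array Hspb1 passed in 7 (0.0195 to 0.0501, highest without normoosmotic replicate 3). Of 18 unfolded protein response genes 1 rose, Sdf2l1 at 0.59 ± 0.11, and adjusted over the list alone 1 rose and 2 fell (0.137). Of 22 ATF4 response genes 1 rose, also adjusted over the list alone (0.669), namely Chac1, a glutathione-degrading enzyme, at 0.79 ± 0.19, with calls in 3 (0.0184 to 0.0862, highest without normoosmotic replicate 3) of the 8 fits. Of 17 NRF2 targets 1 rose, Akr7a3 at 0.93 ± 0.24, and adjusted over the list alone 3 rose and 1 fell. Akr7a3 passed in 2 (0.0193 to 0.113, highest without normoosmotic replicate 3) of the 8 fits, and not after median centring (0.0537). The NRF2 list gave 0.137, but 0.0111 without normoosmotic replicate 1 and 0.0328 without hypoosmotic replicate 3. Of 23 autophagy and lysosome genes 3 fell and 0 rose, also adjusted over the list alone (0.482). They were Atg16l1 (-0.45 ± 0.10), the autophagy receptor gene Sqstm1 (-0.47 ± 0.11) and the mitophagy receptor gene Bnip3l (-0.50 ± 0.13), with calls in 6 (0.0303 to 0.0625, highest without normoosmotic replicate 3), 3 (0.0171 to 0.0879, highest without normoosmotic replicate 3) and 2 (0.0245 to 0.0959, highest without normoosmotic replicate 1) of the 8 fits. Sqstm1 had 0.0501 after a further quantile normalization.

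Of 20 hypoxia-regulated genes 3 rose and 1 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.435). Mxi1 (0.65 ± 0.15 SE), the glucose transporter gene Slc2a1 (0.72 ± 0.19) and the lactate dehydrogenase gene Ldha (0.61 ± 0.16) rose, and the histone demethylase gene Kdm3a (-0.45 ± 0.10) fell. Of the 8 fits without 1 array, Mxi1 passed in 3 (0.00982 to 0.0666, highest without normoosmotic replicate 1), Kdm3a in 3 (0.0257 to 0.0751, highest without normoosmotic replicate 3), Ldha in 2 (0.0391 to 0.139, highest without normoosmotic replicate 3) and Slc2a1 in 1 (0.0426 to 0.107, highest without normoosmotic replicate 2). After median centring neither Slc2a1 (0.0508) nor Ldha (0.0726) passed, Slc2a1 also missed with array weights (0.0515) and a further quantile normalization (0.0506), and Mxi1 missed with its probe sets averaged (0.0668). Among 15 BMP and TGF-beta targets 2 rose and 1 fell, also adjusted over the list alone (0.579), namely the inhibitory Smad6 at 0.46 ± 0.10, Id4 at 0.90 ± 0.20 and the pseudoreceptor gene Bambi at -0.63 ± 0.13. They passed in 4 (0.0344 to 0.0582, highest without normoosmotic replicate 1), 6 (0.0158 to 0.0585, highest without hypoosmotic replicate 2) and 7 (0.0176 to 0.0586, highest without normoosmotic replicate 3) of the 8 fits. Of 16 p53 targets 1 rose and 1 fell, or 2 and 1 adjusted over the list alone (0.607). Perp, a desmosomal membrane protein, rose by 0.46 ± 0.11 and the nuclease gene Aen fell by 0.69 ± 0.15, with calls in 3 (0.0331 to 0.0802, highest without normoosmotic replicate 3) and 5 (0.0203 to 0.0600, highest without normoosmotic replicate 3) of the 8 fits. Among the 5 measured genes of the Mediator kinase module Med13 fell by 0.56 ± 0.10, with a call in all 8 fits, also adjusted over the list alone. The list median was 0.01, its mean -0.09 and the test pointed down (0.572). None of 17 circadian genes passed, also adjusted over the list alone, and 5 had an unadjusted p under 0.05 (limma), led by Tef at -0.55 ± 0.16 (adjusted p = 0.0742, and 0.0465 without normoosmotic replicate 2). That list gave 0.241, and 0.0455 without hypoosmotic replicate 3.

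Among the 10 cell type lists, that of sinusoidal endothelium passed with an adjusted p of 0.0112 (camera), against an adjusted p of 0.735 with an estimated correlation. Of 12 measured members 2 rose and 1 fell, or 4 and 1 adjusted over the list alone, with a median of 0.32. Kdr, a VEGF receptor, rose by 0.66 ± 0.15 (SE) and the nuclease gene Dnase1l3 by 0.82 ± 0.20, while Oit3 fell by 0.46 ± 0.11. Of the 8 fits without 1 array, Kdr passed in 2 (0.0254 to 0.0654, highest without normoosmotic replicate 1), Dnase1l3 in 2 (0.0237 to 0.0899, highest without hypoosmotic replicate 2) and Oit3 in 1 (0.0279 to 0.0782, highest without hypoosmotic replicate 1). Oit3 had 0.0506 after a further quantile normalization. Of 15 macrophage markers 1 rose, also adjusted over the list alone, and the list gave 0.160, but 0.0342 without hypoosmotic replicate 4. It was Lyz2, lysozyme, from 5.58 ± 0.27 to 6.57 ± 0.17, with a call in all 8 fits. Of 14 stellate cell and fibroblast markers 1 rose, also adjusted over the list alone, with a median of 0.27. It was Colec11, at 0.48 ± 0.12, with calls in 2 (0.0349 to 0.107, highest without hypoosmotic replicate 2) of the 8 fits, and not past the threshold after median centring (0.0574). That list gave 0.116, and 0.00416 without hypoosmotic replicate 4.

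Markers of the hepatocytes themselves did not pass in any of 15 genes, also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (limma). This was Hnf4a, the nuclear receptor of hepatocyte identity, at 0.48 ± 0.18 (SE, adjusted p = 0.146). Their median was 0.01, their mean 0.02 and the test pointed down (camera adjusted p = 0.974). Of 12 periportal markers 1 rose, namely Arg1, and of 12 pericentral markers 2 rose, namely the ammonia channel gene Rhbg (0.51 ± 0.12) and the transcription factor gene Tbx3 (0.60 ± 0.16), also adjusted over the list alone. The 2 zonal lists had medians of 0.18 and 0.17, with adjusted p-values of 0.364 and 0.558. Of the 8 fits without 1 array, Rhbg passed in 3 (0.0232 to 0.0967, highest without normoosmotic replicate 3) and Tbx3 in 1 (0.0246 to 0.140, highest without normoosmotic replicate 3), and Tbx3 did not after median centring (0.0562), after a further quantile normalization (0.0573) or with an intensity trend (0.0502). None of 10 cholangiocyte, 11 neutrophil or 15 lymphocyte markers passed, also adjusted over the list alone. Their counts at an unadjusted p under 0.05 (limma) were 1, 0 and 0, their medians 0.03, -0.05 and -0.02, and their adjusted list p-values 0.850, 0.579 and 0.819. The smallest p-values in these were those of Cdh1 (-0.38 ± 0.15, adjusted p = 0.179, and 0.0356 without normoosmotic replicate 1), Ncf1 (-0.36 ± 0.19) and Prf1 (-0.31 ± 0.16). Of 7 red cell genes 1 rose, also adjusted over the list alone (list adjusted p = 0.669), namely Ahsp, at 0.56 ± 0.14. Its level was 1.56 ± 0.12 in normoosmotic livers, near the 1.82 that was the median of the odorant receptor genes, and it passed in 2 (0.0165 to 0.0932, highest without normoosmotic replicate 1) of the 8 fits and neither after median centring (0.0602) nor after a further quantile normalization (0.0649).

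**Figure D3:**
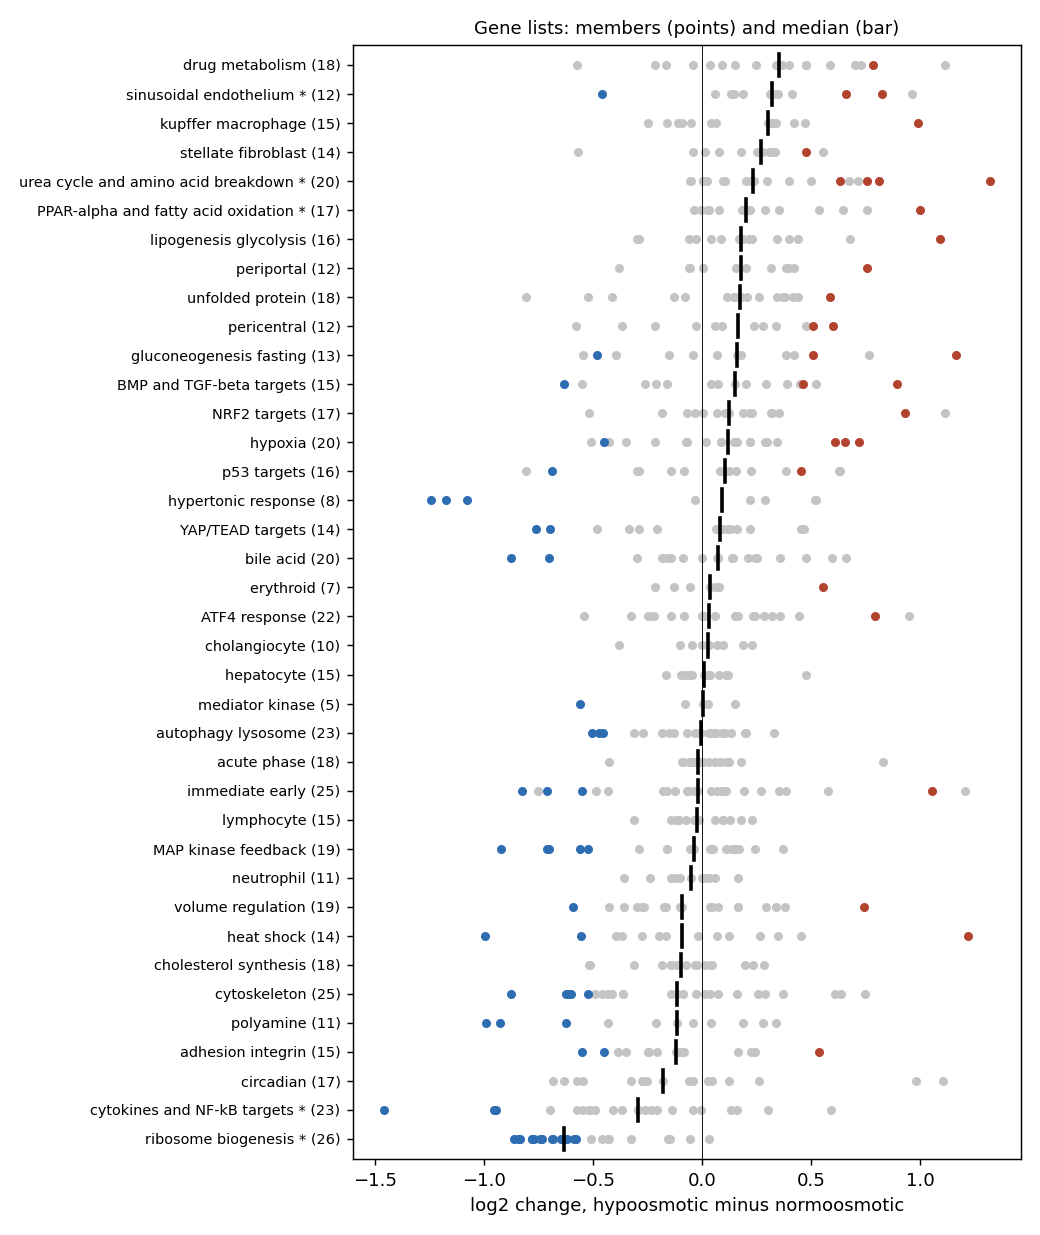
Log2 change of every measured member (points) of the 38 gene lists, hypoosmotic minus normoosmotic, with the list median as a black bar, the number of measured members in parentheses and an asterisk on the 5 lists with a camera adjusted p under 0.05. Red points rose and blue points fell past an adjusted p of 0.05, grey points did not pass, and ribosome biogenesis, with a median of -0.64 and 15 falls, lies lowest.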

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

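The tests weighed here had their criteria written before their results were seen, except that the histone, S-phase and mitosis families were chosen after the largest changes were known, with the S-phase gene Rrm2 among these. In 16 of 246 groups of 4 arrays checked for the named genes, 1 array lay far from the other 3, by a gap above Dixon's 95% critical share of the group's range. Chance alone gives about 1 in 20 such groups.

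Among normoosmotic arrays, replicate 1 stood apart for Cp (12.15, others 11.86 to 11.90), Cdh1 (8.60, others 9.17 to 9.26) and Ahsp (1.38, others 1.60 to 1.64). Replicate 2 stood apart for Cxcl2 (10.55, others 10.17 to 10.22) and Cyp7b1 (6.50, others 5.94 to 6.03). Replicate 3 did so for S1pr1 (5.28, others 6.58 to 6.84), Dusp16 (9.51, others 9.11 to 9.15) and Ncf1 (4.52, others 4.84 to 4.90). Replicate 4 did so for Klf10 (5.17, others 5.75 to 5.81), Arg1 (8.86, others 9.42 to 9.5) and Gpt2 (6.49, others 6.31 to 6.33).

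Among hypoosmotic arrays, replicate 2 stood apart for Tef (4.61, others 4.49 to 4.51). Replicate 3 did so for Gpcpd1 (7.18, others 6.85 to 6.89) and H3f3b (10.68, others 10.18 to 10.25), and replicate 4 for Itgb3 (5.98, others 6.34 to 6.38) and F3 (6.40, others 7.05 to 7.10).

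Among probe sets with no gene name here, which the comparisons of genes did not use, 288 of 11963 passed when all probe sets were tested together with limma, 93 higher and 195 lower. The largest change among them was in probe set 10897543, which went from 4.83 to 8.22 (log2 change 3.39, SE 0.25, n = 4 each, adjusted p = 0.000622) and exceeded that of every named changed gene.

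More genes fell than rose after hypoosmotic perfusion, 670 against 356. Only 1 of the 35 splits of the 8 arrays into groups of 4, the real one, gave as many changed genes as 1026. The highest of the others gave 1. Those splits mix both groups, so a difference between the groups adds to their spread and lowers their counts. With 1 in 35 as the smallest possible share, this test cannot exclude chance for the count. If the scaling of the arrays were the cause, the excess of falls would largely vanish under another scaling. The share of falls was 60.2% after a further quantile normalization and 75.7% after median centring, against 65.3% as deposited. The excess thus stayed under both, though its size moved with the scaling. Both started from the deposited values and cannot undo a scaling within RMA, so this test cannot exclude that scaling as a cause. A transcriptional effect of the lower osmolarity stays open as a hypothesis, as do differences between the perfusions that the labels do not record.

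The cytokine genes Il1a, Il1b and Cxcl2 fell. Fewer macrophages in the hypoosmotic livers would lower the markers of these cells by about as much, but the median change of 15 macrophage markers was 0.30 (95% bootstrap interval -0.05 to 0.34), while the median of the cytokine genes that fell was -0.95. That -0.95 came from the 3 of 23 list members picked because they fell, so it was low by construction. The whole list had a median of -0.29. The interval resampled markers, not arrays, so it leaves out the spread between samples. The markers as a set were not lower, which argues against a loss of macrophages only as the whole cause. A lower expression per cell under hypoosmotic buffer may remain, as may a change in other cells that make these cytokines, and neither was tested.

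Of 32 histone genes 10 rose and 0 fell, with a median of 0.37, and the family passed with a camera adjusted p of 1.39e-08, against an adjusted p of 0.135 with an estimated correlation. If more cells were in S phase, S-phase genes would be higher, and the median of 28 such genes was 0.12 (95% bootstrap interval 0.03 to 0.23), which met both bounds set in advance, above 0 for this explanation and below the histone median against it. The bounds were badly set, since 1 value could meet both, and the second assumed that S-phase genes move as much as histone genes while their members went both ways, 3 up and 2 down. Mitosis genes had the same median of 0.37 over 15 members and passed as a family by camera (adjusted p = 0.000955) but not with an estimated correlation (adjusted p = 0.529), and 0 members passed singly (limma). More cells in S phase and an osmolarity effect on histone transcripts cannot be told apart here, and signal shared between similar histone genes may add to either.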

How the results depend on the processing

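The gene families and the count above a background level were tests chosen after seeing the data; the other alternatives were planned. The number of changed genes, 1026, was 968 to 1183 under an intensity trend, array weights, both scalings, the dim-gene filter and averaged probe sets. With all probe sets tested together 1118 probe sets passed. Of these 288 had no gene name here, so this count is not one of genes. Genes higher numbered 356, and 235 after median centring, where every change shifts by the difference in medians and the median change over all genes was -0.03. Against a fold change of 1.2 the counts were 83 changed, 23 higher and 60 lower, a stricter question by construction. Leaving out 1 array gave 468 to 1051 changed genes, 137 to 392 higher and 331 to 659 lower, lowest without normoosmotic replicate 3 and highest without hypoosmotic replicate 4 (the cause was not tested).

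Of the 38 lists, 3 passed as higher and 2 as lower. These calls held under array weights, both scalings, the dim-gene filter and averaged probe sets, while the filter left too few neutrophil markers for a test and left out Ahsp. A variance trend does not enter the set test. With an estimated correlation 0 were higher and 0 lower, and 0 lists had an unadjusted p under 0.05. With fry, 0 were higher and 0 lower by the directional p, and 10 had an unadjusted p under 0.05, while 26 passed by the mixed p, which asks whether members change in either direction. The cause was not tested. Leaving out 1 array gave 2 to 5 lists higher and 2 to 4 lower.

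With the replicate number as a term (replicate block), 1029 genes changed, 417 higher and 612 lower, of which 848 were shared with the 1026. Among the genes named in the text the block ended 7 calls (Dusp6, Dusp16, Klf6, Bnip3l, Kdm3a, Tbx3 and Ndufa3) and added 2 (Cp and Mvd), and 1 more list passed, drug metabolism. Arrays with the same number had correlations of their deviations between 0.00613 and 0.257, and 6 of 8 arrays correlated best with their own number, a hint from the data, not the design.

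Of the genes named in the text, 0 changed direction past the threshold under any alternative. Over all of them, leaving out 1 array ended a call 239 times and added one 3 times. The ribosomal protein family, with a median of -0.02 that did not pass, had medians from -0.0658 without hypoosmotic replicate 1 to 0.0738 without hypoosmotic replicate 4, where it passed as higher (camera adjusted p = 0.0378), a reversed direction whose cause was not tested.

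Signal over background limits the dimmest genes. Odorant receptor genes had a median level of 1.82 and a 95th percentile of 3.04. Of the 1026 changed genes, 1020 had a mean above that percentile in at least 1 group, 352 higher and 668 lower, while 6 did not. The same held for 10849 of the 14511 tested genes. A gene with only 1 group above the percentile is counted as above it. Background correction and a slide term were not run, since scanner files were not used here.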

Other observations

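All families here were chosen after the largest changes were known, so their tests describe these data and are not independent evidence. Histone genes rose as a family in hypoosmotic livers. Of 32 measured members 10 rose and 0 fell (median 0.37, camera adjusted p = 1.39e-08, and adjusted p = 0.135 with an estimated correlation). Beside the linker histone gene H1f4, the core histone genes Hist1h2bq (1.17 ± 0.16 SE), Hist1h4b (1.06 ± 0.16), Hist1h2ail1 (0.79 ± 0.14) and H3f3b (0.74 ± 0.14) rose, and the members resemble each other in sequence. Hist1h2ail1 did not pass with its probe sets averaged (0.0529). The family median was 0.33 to 0.37 under both other scalings, and the number that rose was 6 without normoosmotic replicate 1 or normoosmotic replicate 3.

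Of 78 splicing factor genes 14 fell and 0 rose (median -0.18, camera adjusted p = 3.17e-07, and adjusted p = 0.305 with an estimated correlation). Luc7l3, a component associated with the U1 particle, went from 6.92 ± 0.26 to 5.72 ± 0.25 (SD, n = 4 each). Srsf6, a serine and arginine rich splicing factor, fell by 1.06 ± 0.14 (SE), Srpk1, a kinase of such factors, by 1.04 ± 0.13 and the splicing regulator gene Rbm25 by 0.83 ± 0.13. The number that fell was 8 without normoosmotic replicate 2 or hypoosmotic replicate 2, and 9 without normoosmotic replicate 3, normoosmotic replicate 4 or hypoosmotic replicate 1. Subunits and assembly factors of the respiratory chain and ATP synthase were higher as a family of 80 (median 0.18, camera adjusted p = 3.17e-07, and adjusted p = 0.502 with an estimated correlation), with 2 that rose, Ndufaf1 (0.73 ± 0.15) and Ndufa3 (0.68 ± 0.17), and 16 at an unadjusted p under 0.05 (limma). Ndufa3 passed in 2 of the 8 fits without 1 array (0.0385 to 0.101, highest without hypoosmotic replicate 1) and not after median centring (0.0629).

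Other families were tested in the same way. Over all families, 3 of the camera calls did not pass by the directional p of fry. Mitosis genes had a median of 0.37 over 15 members with 0 past the threshold and 4 at an unadjusted p under 0.05 (limma), at a median level of 3.52 (camera adjusted p = 0.000955, and adjusted p = 0.529 with an estimated correlation). S-phase genes had 3 rises and 2 falls among 28 (camera adjusted p = 0.0282, and adjusted p = 0.502 with an estimated correlation), with 0.0852 without normoosmotic replicate 3, 0.0635 without hypoosmotic replicate 1, 0.136 without hypoosmotic replicate 3 and 0.0641 after a further quantile normalization. Of 27 tRNA synthetase genes 1 rose and 4 fell (camera adjusted p = 0.132, and 0.0327 without normoosmotic replicate 3 and 0.0449 without hypoosmotic replicate 1). Of 39 proteasome genes 0 rose and 1 fell (0.198, and 0.0469 without hypoosmotic replicate 2), and of 51 genes of general and elongation factors of transcription, picked by symbol and with the RNA polymerase I factor gene Taf1d among them, 3 rose and 10 fell (0.235). Of 151 zinc finger genes 6 rose and 10 fell (0.423), of 1240 odorant receptor genes 1 rose and 0 fell (0.703), and of 64 ribosomal protein genes 0 passed, with 0 at an unadjusted p under 0.05 (limma, camera adjusted p = 0.704).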
